A study of Mus musculus with 6 samples.

How the data were processed

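Per the labels' protocols, a piece of visceral fat was taken from the abdomen of each mouse, total RNA was isolated, and libraries were made with the NEBNext Ultra II RNA kit and sequenced on an Illumina NextSeq instrument. How messenger RNA was selected is not given in the sources used here. Per the submitters' processing notes, the tools named were Trimmomatic 0.36, FastQC, HISAT2 2.0.4, SAMtools 0.1.19 and HTSeq, and the genome build was GRCm38 (mm10). The annotation, the settings and the strand setting of the counting are not given in the sources used here, and the kit is not said to keep strand, so levels of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies.

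The authors deposited 1 table of whole-number counts per library, with Ensembl gene identifiers and no normalization. Each table held 46603 identifiers, of which 26398 had at least 1 count in any library, and 46091 were matched to the GENCODE M21 annotation of the same build for names, positions and biotypes. The 512 unmatched identifiers held 0.033% of the counts. Entries that name no gene numbered 0. Pearson's r of log2 CPM lay between 0.961 and 0.979 within groups and between 0.934 and 0.968 between groups. The chi-square per degree of freedom of library pairs within a group was at least 38.4, so no 2 libraries agreed within sampling noise and each counted as 1 sample. The first principal component held 48.1% of the variance and separated the groups, with NM1 KO replicate 1 farthest from WT. Mean total counts were 27537400 ± 3353750 (SD, n = 3) in WT and 30758300 ± 3031720 in NM1 KO, with an exact two-sided permutation p of 0.3, and 3 against 3 cannot give a p under 0.1. The mitochondrial share was 2.14% ± 0.160 in WT and 2.03% ± 0.679 in NM1 KO (exact permutation p = 0.8), and the ribosomal protein share 1.77% ± 0.0950 and 1.69% ± 0.0685 (exact permutation p = 0.5). A mean of 21211 genes was detected in WT and 21619 in NM1 KO (exact permutation p = 0.2).

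Samples were grouped by the genotype in their labels. Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM size factors, the quasi-likelihood fit with robust dispersion and genotype as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE values of genes are the log2 fold change divided by the square root of the F statistic. SE values of list medians come from resampling the members of the list and hold no spread between samples. CPM uses TMM-scaled library sizes. The common biological coefficient of variation was 25.3%. Gene lists for 50 pathways and cell types were written before the data were examined, and 47 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Cell type lists describe levels of markers in bulk tissue and name no cells. On simulated counts for this comparison, with 200 of 15568 genes changed, edgeR recovered 38% of the genes changed 2-fold and 75% of those changed 4-fold, and 9.6% of its calls were genes that had not been changed.

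The genes named in the text followed a rule set before the data were examined. It took Myo1c, then Pparg, Cebpa, Adipoq, Lep, Fasn, Ucp1, Adgre1, Tnf, Il6, Ccl2 and Col1a1 whatever their values. It added the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM, named symbols that are not pseudogenes and non-overlapping ranges. It then took, from each list that passed camera or had at least 3 called members, the 3 members with the smallest p and a mean of at least 1 CPM, or 4 for the leading lists, and Xist and Ddx3y. Not every gene it selects is printed, and some called genes are not reported here.

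The alternatives were RLE and upper-quartile size factors, library totals alone, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, non-robust dispersion, the replicate number as a block, leaving out each library in turn, protein-coding genes only, DESeq2 1.42.0 and limma-voom with sample quality weights. A correction that enters each library's smooth trend on GC content and exonic length (natural splines with 5 degrees of freedom) as an offset was added after seeing the data. Figures were drawn with matplotlib 3.10.9.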

Results

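RNA was sequenced from visceral adipose tissue, the fat of the abdominal cavity, of C57/Bl6 mice aged 18 months. The 6 libraries fell into 2 groups by genotype, with 3 from wild-type mice (WT) and 3 from mice lacking nuclear myosin 1 (NM1 KO). Nuclear myosin 1 is an isoform of the unconventional motor protein encoded by Myo1c and acts in the nucleus in transcription and chromatin organization. The total gene counts were 26705606, 31228723 and 24677758 in WT replicates 1 to 3, and 31211682, 33537818 and 27525446 in NM1 KO replicates 1 to 3. The labels number the replicates but do not say that each came from a separate animal, so the p-values measure only the spread between these samples, which may be technical. The labels do not give the sex either. Xist, the X-inactivation RNA made in female cells, lay at 0.290 CPM (counts per 1e6 counts) or lower in every library, and the Y-linked gene Ddx3y lay between 30.9 and 118 CPM. Below, CPM values are means ± SD with n = 3 per group, log2 fold changes are NM1 KO minus WT with their SE, and a gene was called when the adjusted p of edgeR's quasi-likelihood test was under 0.05.

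The targeted locus was examined first. Myo1c (ENSMUSG00000017774, chromosome 11, 75650504 to 75673910 on GRCm38) had 801, 759 and 801 CPM in WT replicates 1 to 3, and 452, 697 and 551 CPM in NM1 KO replicates 1 to 3. The log2 fold change was -0.47 ± 0.17 with an adjusted p of 0.151, so Myo1c was not called. Without NM1 KO replicate 2 the log2 fold change was -0.65 with an adjusted p of 0.0391, and limma-voom with quality weights gave an adjusted p of 0.0382. The count covers every isoform of the locus, and which part of the locus was altered is not given in the sources used here, so these values do not check the knockout. The 18 tested genes of the B-WICH complex and other nuclear myosin partners had a median log2 fold change of -0.058 (camera adjusted p = 0.773) with 0 called by edgeR, 5 at an unadjusted p under 0.05 (3 higher and 2 lower), 0 called by DESeq2 and 2 by limma-voom (1 higher and 1 lower). The mean of this list was 0.024, of the opposite sign to the median and to camera's direction, which was lower.

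The comparison of NM1 KO with WT asks which transcripts of the aged fat depot differ when nuclear myosin 1 is missing. Of 15828 genes tested, 673 were called, 441 higher and 232 lower in NM1 KO. Macrophage, matrix and cholesterol synthesis genes were among those that rose, and genes of vascular endothelium among those that fell. The change was over 2-fold for 257 of the genes that rose and 135 of those that fell. The CPM ranges of the groups did not overlap for any of the 673, nor for 29.9% of all tested genes, where chance gives 10%. The number of calls depended on single libraries. It was 37 without WT replicate 1, 4 without WT replicate 2, 1 without WT replicate 3, 244 without NM1 KO replicate 1, 1654 without NM1 KO replicate 2 and 5 without NM1 KO replicate 3. The 4 were Pdpr, Cbl, Otop1 and Gm8797, the 1 was Cbl, and the 5 were Ltbp2, Cpxm2, Cbl, 2610507I01Rik and Gm8797, most of which are named here after their values were seen. All 673 genes kept the sign of their fold change in each of these fits. Removing 1 library can hardly turn a sign where ranges do not overlap, so the kept signs do not measure stability. Of the 58 called genes that the naming rule selected, 6, 1, 0, 33, 56 and 1 were still called in the same order of removals. All 58 kept their sign, to which the same limit applies.

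The fold changes also followed the GC content of the genes. Across 13933 protein-coding genes, which are not independent replicates, Spearman's rho of the log2 fold change was -0.37 with GC content and 0.23 with exonic length. Genes called higher had a median GC content of 47.6%, and genes called lower 55.6%. Expression deviated with GC content by a rho of 0.349, 0.258 and 0.145 in WT replicates 1 to 3, and by -0.430, 0.239 and -0.457 in NM1 KO replicates 1 to 3, so NM1 KO replicate 2 had the sign of the WT libraries (exact permutation p = 0.2 for the groups, two-sided, where 0.1 is the smallest possible). In a fit with each library's trend on GC content and length removed, chosen after seeing the data, 764 genes were called and 518 of the 673 remained called, all in the same direction.

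**Figure D1:**
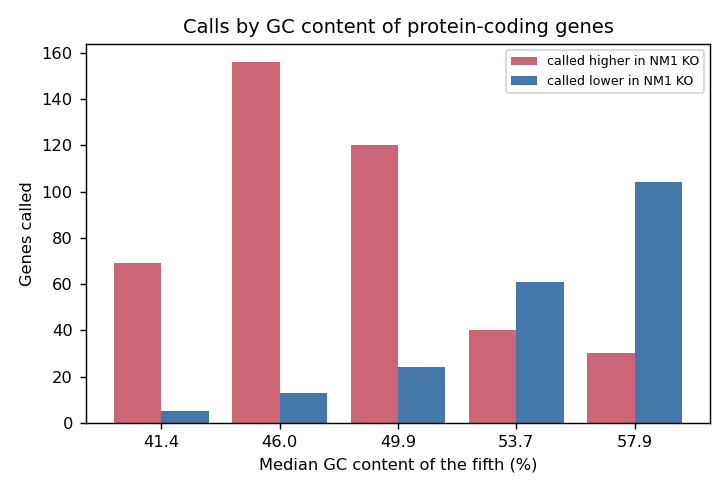
Number of protein-coding genes called higher (red) or lower (blue) in NM1 KO, in 5 bins of equal size by GC content, given by the bin's median (x axis, percent). The bin with the lowest GC content held 69 higher and 5 lower calls, and that with the highest held 30 higher and 104 lower.

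Genes of blood vessels fell. All 17 tested markers of vascular endothelium had a negative log2 fold change, 11 were called lower, and 16 passed when adjusted over the list alone, with a median of -1.07. Egfl7 (ENSMUSG00000026921, chromosome 2, 26580014 to 26593120), a factor secreted by endothelial cells, fell from 86.0 ± 2.37 to 30.7 ± 6.35 CPM (log2 -1.49 ± 0.16, adjusted p = 0.0176). Eng, an endothelial co-receptor for TGF-beta ligands, fell from 172 ± 19.8 to 81.9 ± 10.2 CPM (log2 -1.07 ± 0.14). Sox18, an endothelial transcription factor, fell by 1.30 on the log2 scale, and Emcn, a sialomucin of capillaries and veins, by 0.89. The list passed camera with an adjusted p of 2.11e-21, and had an adjusted p = 0.328 with an estimated correlation. With the trend on GC content and length removed its median was -1.02. Lists of mesothelium (14 of 15 negative) and erythroid genes (7 of 8 negative), described below, were lower as well. The list of pericytes and smooth muscle also fell (median -0.60, camera adjusted p = 0.000146, adjusted p = 0.328 with an estimated correlation), with 1 of 14 members called and 7 lower when adjusted over the list alone. The called member was Myh11, the smooth muscle myosin heavy chain, at 41.0 ± 1.45 CPM in WT and 21.2 ± 1.98 in NM1 KO (adjusted p = 0.0182). Notch3 (log2 -1.25, adjusted p = 0.0826) and Smtn (log2 -0.58, adjusted p = 0.0745) were not called.

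Among 21 genes of angiogenesis and the hypoxia response, 2 were called lower and 1 higher, and 6 were lower and 4 higher when adjusted over the list alone. Flt1, a receptor for vascular endothelial growth factor, fell from 104 ± 8.52 to 32.7 ± 7.50 CPM, and Vegfa, the growth factor itself, from 374 ± 7.34 to 179 ± 44.9 CPM (log2 -1.07 ± 0.18, adjusted p = 0.0304). Vldlr, the very low density lipoprotein receptor, rose from 87.9 ± 17.7 to 195 ± 43.3 CPM. The list itself did not pass camera (adjusted p = 0.0937), but did without a filter on low counts (adjusted p = 0.0444), without WT replicate 2 (adjusted p = 0.0266) and with the GC and length correction (adjusted p = 0.0411). Lymphatic endothelium had a median of 0.64 and a mean of 0.11, while camera gave it a lower direction (adjusted p = 0.393). Its median was 1.39 without WT replicate 1, 0.047 without WT replicate 2, -0.46 without NM1 KO replicate 1, 1.18 without NM1 KO replicate 2 and -0.14 with the CPM filter. None of its 7 members was called by edgeR, 3 had an unadjusted p under 0.05 (all lower), DESeq2 called 2 and limma-voom 0.

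**Figure D2:**
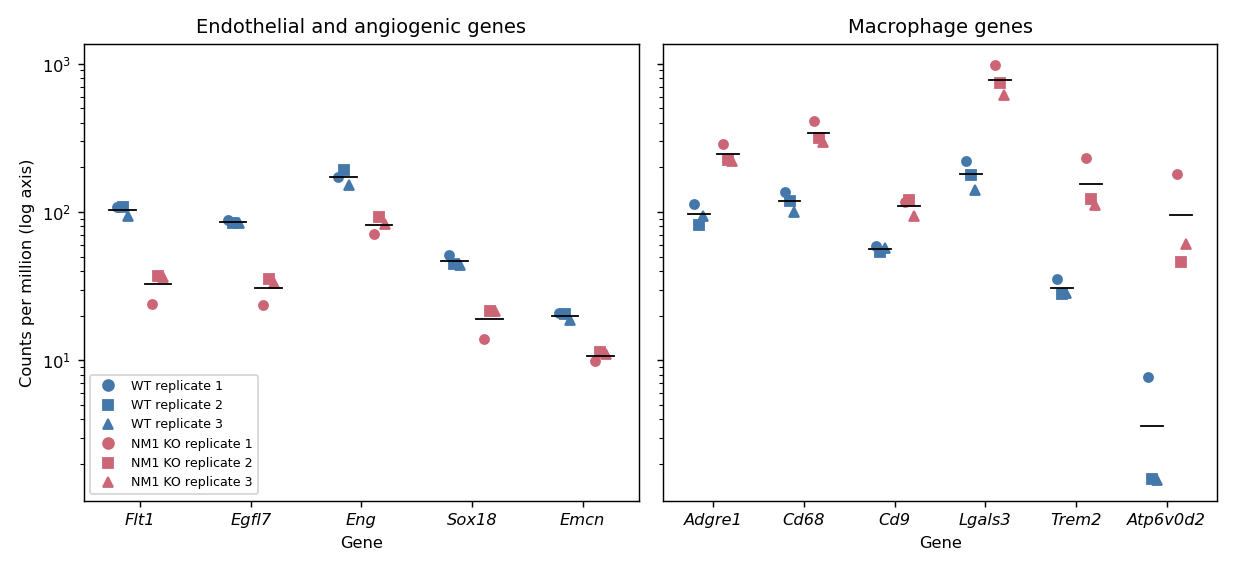
CPM (y axis, log scale) of endothelial and angiogenic genes (left) and macrophage genes (right) in each library, WT in blue and NM1 KO in red, with the replicate given by the marker's shape and the group mean by a black line. Flt1 averaged 104 CPM in WT and 32.7 in NM1 KO, and Trem2 30.7 and 156.

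Macrophage genes rose. Of 19 lipid-associated macrophage genes, which mark macrophages that take up and break down lipid, 8 were called higher and none lower, 16 were higher when adjusted over the list alone, and the median was 1.47. Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor of macrophages, rose from 30.7 ± 4.14 to 156 ± 67.1 CPM (log2 2.34 ± 0.30, adjusted p = 0.0186). Lgals3, which encodes galectin-3, rose from 180 ± 39.7 to 777 ± 188 CPM (log2 2.11 ± 0.23), and Cd9, a tetraspanin, from 56.7 ± 2.41 to 111 ± 14.8 CPM (log2 0.97 ± 0.12). Atp6v0d2, a subunit of the vacuolar proton pump, rose from 3.63 ± 3.55 to 95.2 ± 73.2 CPM (log2 4.72 ± 0.84), with the highest value in NM1 KO replicate 1 (179 CPM). The list passed camera with an adjusted p of 1.69e-18, and had an adjusted p = 0.328 with an estimated correlation. With the trend on GC content and length removed its median was 1.27.

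General macrophage markers rose as well, with 7 of 19 called higher, 12 when adjusted over the list alone, and a median of 0.56 (camera adjusted p = 1.17e-11, adjusted p = 0.328 with an estimated correlation). Adgre1, which encodes the surface protein F4/80, rose from 96.6 ± 16.0 to 245 ± 36.6 CPM (log2 1.34 ± 0.16, adjusted p = 0.0182). Cd68, a lysosomal glycoprotein, rose by a log2 of 1.52 ± 0.17, Tyrobp, a signalling adaptor, by 1.20 ± 0.17, and Ms4a7 by 1.73 ± 0.30. Genes of resident and alternatively activated macrophages went the other way (median -0.995, camera adjusted p = 0.00772, adjusted p = 0.667 with an estimated correlation). None of these 18 genes was called by edgeR over all genes or adjusted over the list alone, while 7 had an unadjusted p under 0.05 (1 higher and 6 lower), and DESeq2 called 5 and limma-voom 3. Timd4, a receptor of tissue-resident macrophages, had a log2 fold change of -1.92 ± 0.50 (adjusted p = 0.0774) and Fcna, a ficolin, one of -1.50 ± 0.39 (adjusted p = 0.0786). Mrc1, the macrophage mannose receptor, had one of 0.86 ± 0.25 (adjusted p = 0.104).

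Genes of MHC class II presentation rose by a median of 0.26 (camera adjusted p = 0.0417, adjusted p = 0.613 with an estimated correlation), with 2 of 12 called and 2 adjusted over the list alone. Ctss, the lysosomal protease cathepsin S, rose from 204 ± 14.4 to 673 ± 217 CPM, and H2-DMb1, a peptide-loading chaperone, from 52.9 ± 0.845 to 78.3 ± 1.16 CPM, while H2-Aa was not called (log2 0.33, adjusted p = 0.374). The list lost its call without WT replicate 1 (median 0.11, adjusted p = 0.165), without NM1 KO replicate 1 (adjusted p = 0.0564) and without NM1 KO replicate 2 (adjusted p = 0.0518). Among 34 pro-inflammatory cytokines, chemokines and genes of their induction, 3 were called higher and 4 when adjusted over the list alone, with a camera adjusted p of 0.0701. That list passed without a filter on low counts (adjusted p = 0.0257), with the GC and length correction (adjusted p = 0.0496), without WT replicate 2 (adjusted p = 0.000173), without NM1 KO replicate 1 (adjusted p = 0.0432) and without NM1 KO replicate 2 (adjusted p = 0.0168). Il1rn, the interleukin-1 receptor antagonist, rose by a log2 of 2.08 ± 0.25, Ccl3, a chemokine whose gene lies 7.97 Mb from Myo1c, by 3.42 ± 0.62 from 0.240 ± 0.182 CPM, and Vcam1, an adhesion molecule for leukocytes, by 1.35 ± 0.25. Tnf (log2 0.82 ± 0.29, adjusted p = 0.152) and Ccl2 (log2 0.16 ± 0.55, adjusted p = 0.889) were not called, and Il6 was at 0.399 ± 0.492 CPM in WT and 0.0638 ± 0.0855 in NM1 KO, too low to test.

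Genes of T cells and of NK and cytotoxic cells lay higher in the median, with few calls. The T cell list rose (median 1.05, camera adjusted p = 0.00271, adjusted p = 0.667 with an estimated correlation), with 1 of 19 genes called and 1 adjusted over the list alone. That gene, Il7r, the interleukin-7 receptor, rose from 4.18 ± 0.150 to 23.7 ± 18.0 CPM (log2 2.50 ± 0.52, adjusted p = 0.0472, and log2 1.71 without NM1 KO replicate 1). Cd28, a T cell co-receptor, had a log2 fold change of 1.99 ± 0.78 (adjusted p = 0.181). Genes of NK and cytotoxic cells rose with a median of 1.24 (camera adjusted p = 0.00769, adjusted p = 0.667 with an estimated correlation). None of these 10 was called by edgeR, 2 were higher when adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 1. Their transcription factor Eomes had a log2 fold change of 2.48 ± 0.67 (adjusted p = 0.0850) and Prf1, perforin, one of 1.80 ± 0.49 (adjusted p = 0.0850). The NK list lost its call without NM1 KO replicate 3 (adjusted p = 0.0675) and with the CPM filter (adjusted p = 0.123). Both lists stood at the WT level in NM1 KO replicate 2, with list medians against the WT mean of 1.58, -0.21 and 1.15 for T cells and 1.32, 0.11 and 1.84 for NK cells in NM1 KO replicates 1 to 3. When 1 library was left out, the T cell median lay between 0.61 and 1.32. That of NK cells lay between 0.96 and 1.87. B cell genes had a median of 0.55 (camera adjusted p = 0.519), with 0 of 15 called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. The B cell medians against the WT mean were 1.91, -0.56 and -0.76 in NM1 KO replicates 1 to 3. Camera's direction for B cells was lower without NM1 KO replicate 1 (median -0.48, adjusted p = 0.00251) and higher without NM1 KO replicate 3 (adjusted p = 0.0289).

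Genes of the extracellular matrix rose, with 4 of 38 called higher, 8 adjusted over the list alone, and a median of 0.43 (camera adjusted p = 2.64e-06, adjusted p = 0.602 with an estimated correlation). Col5a2, a fibrillar collagen chain, rose from 194 ± 15.6 to 354 ± 38.4 CPM (log2 0.86 ± 0.12, adjusted p = 0.0217). Col8a1, a short-chain collagen, rose by a log2 of 1.17 ± 0.20, and Lum, the proteoglycan lumican, by 1.36 ± 0.25. The remaining called member, Col12a1, named after its value was seen, rose by 1.73 ± 0.32. Col1a1, the main chain of type I collagen, was not called (760 ± 96.1 against 1243 ± 223 CPM, log2 0.71 ± 0.17, adjusted p = 0.0646). Matrix proteases, their inhibitors and TGF-beta signalling rose by a median of 0.41 (camera adjusted p = 0.000146, adjusted p = 0.328 with an estimated correlation), with 2 of 31 called higher and 1 lower, and 10 higher and 1 lower when adjusted over the list alone. Ltbp2, a latent TGF-beta binding protein of elastic fibres, rose from 50.8 ± 6.54 to 189 ± 18.8 CPM (log2 1.89 ± 0.14, adjusted p = 0.00825). Adamts12, a metalloprotease, rose by a log2 of 2.19 ± 0.29, while Mmp9, gelatinase B, fell from 48.6 ± 14.2 to 12.2 ± 4.43 CPM (log2 -1.99 ± 0.31).

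Of 19 markers of fibro-adipogenic progenitors, the stromal cells that give rise to fat cells and fibroblasts, 3 rose, with 3 adjusted over the list alone. Besides Lum these were Pdgfra, the receptor that marks these cells (88.6 ± 8.91 against 159 ± 16.1 CPM, adjusted p = 0.0227), and Prrx1, a mesenchymal transcription factor (log2 0.97 ± 0.20). The list had a median of -0.044 and a mean of -0.15, but camera's direction was higher (adjusted p = 0.707). Mesothelium, the lining of the abdominal organs, fell (median -0.49, camera adjusted p = 0.00135, adjusted p = 0.658 with an estimated correlation), with 2 of 15 markers called and 2 adjusted over the list alone. Wt1, a mesothelial transcription factor, fell from 64.2 ± 8.26 to 34.5 ± 2.60 CPM, and Nkain4 from 47.3 ± 9.86 to 22.6 ± 4.76 CPM. Krt19, a keratin, was not called (log2 -1.42 ± 0.43, adjusted p = 0.112).

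**Figure D3:**
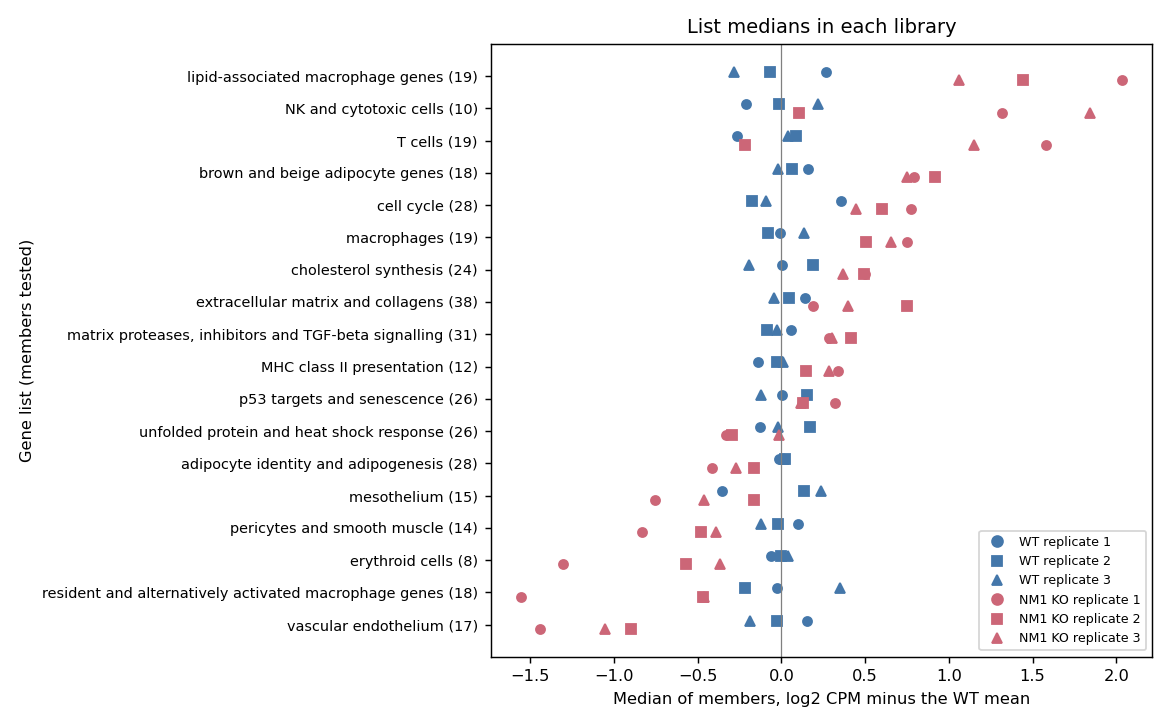
Median over the members of each of the 18 gene lists that passed camera (y axis, members tested in brackets) in each library, as log2 CPM minus the WT mean (x axis), WT in blue and NM1 KO in red. Vascular endothelium lay at -1.44, -0.90 and -1.05 in NM1 KO replicates 1 to 3, and lipid-associated macrophage genes at 2.04, 1.44 and 1.06.

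Genes of adipocyte identity and adipogenesis fell slightly as a list (median -0.28, camera adjusted p = 0.00290, adjusted p = 0.613 with an estimated correlation). The list's median was -0.17 without NM1 KO replicate 1. None of its 28 members was called by edgeR over all genes or adjusted over the list alone, while 10 had an unadjusted p under 0.05 (1 higher and 9 lower), DESeq2 called 8 and limma-voom 4. Pparg, the master regulator of fat cell formation, was at 196 ± 48.0 CPM in WT and 209 ± 41.2 in NM1 KO (log2 0.090 ± 0.22, adjusted p = 0.836). Cebpa, its partner transcription factor, had a log2 fold change of -0.15 ± 0.18 (adjusted p = 0.649), Adipoq, adiponectin, one of -0.22 ± 0.15 (adjusted p = 0.413), and Fasn, fatty acid synthase, one of -0.19 ± 0.33 (adjusted p = 0.771). Lep, the satiety hormone leptin, was at 1946 ± 864 CPM in WT and 4346 ± 546 in NM1 KO (log2 1.16 ± 0.31, adjusted p = 0.0805) and was not called. Adrb3, the beta-3 adrenergic receptor of fat cells, was at 796 ± 64.7 and 201 ± 134 CPM (log2 -1.99 ± 0.52, adjusted p = 0.0804), and Cfd, adipsin, at 6128 ± 3038 and 1975 ± 824 CPM (adjusted p = 0.0902).

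Brown and beige adipocyte genes rose by a median of 1.00 (camera adjusted p = 9.18e-06, adjusted p = 0.287 with an estimated correlation), with 2 of 18 called and 6 adjusted over the list alone. Cidea, a lipid droplet protein, rose from 2.23 ± 0.239 to 8.39 ± 3.08 CPM (log2 1.91 ± 0.32), and Otop1, a proton channel, from 3.17 ± 1.40 to 20.1 ± 1.30 CPM (log2 2.67 ± 0.35), while Gk, glycerol kinase, was not called (log2 0.88 ± 0.21, adjusted p = 0.0612). Ucp1, the uncoupling protein of brown fat, was at 0.0240 ± 0.0212 CPM in WT and 0.316 ± 0.249 in NM1 KO, too low to test. Cholesterol synthesis genes rose (median 0.44, camera adjusted p = 0.000569, adjusted p = 0.658 with an estimated correlation), with 4 of 24 called and 9 adjusted over the list alone. The sterol enzymes Msmo1 and Hsd17b7 rose by log2 values of 0.61 ± 0.10 and 0.83 ± 0.16, and Stard4, a sterol carrier, by 0.74 ± 0.14. Of 31 genes of insulin signalling and glucose uptake, 4 were called higher and 1 lower, and 5 and 1 when adjusted over the list alone, with a camera adjusted p of 0.0743. It passed without a filter (adjusted p = 0.0287), without WT replicate 1 (adjusted p = 0.0390) and without NM1 KO replicate 1 (adjusted p = 0.0296). Grb14, an adaptor that binds the insulin receptor, rose from 18.8 ± 5.94 to 48.5 ± 3.83 CPM (log2 1.37 ± 0.23). The kinases Gsk3b and Pdpk1 rose by log2 values of 0.64 ± 0.090 and 0.59 ± 0.088, which were 0.40 and 0.33 at their lowest over the alternatives. The other called members, named after their values were seen, were Irs1, an insulin receptor substrate, at 0.94 and the kinase Rps6kb2 at -0.67.

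Cell cycle genes rose as a list (median 0.62, camera adjusted p = 7.58e-05, adjusted p = 0.629 with an estimated correlation). None of its 28 members was called by edgeR, 6 were higher when adjusted over the list alone, 12 had an unadjusted p under 0.05, and DESeq2 called 6 and limma-voom 3. Top2a, the topoisomerase of dividing cells, was at 6.20 ± 1.57 CPM in WT and 15.1 ± 4.77 in NM1 KO (adjusted p = 0.0599). Genes of p53 targets and senescence rose by a median of 0.19 (camera adjusted p = 0.00772, adjusted p = 0.629 with an estimated correlation), with 3 of 26 called higher, and 6 higher and 1 lower adjusted over the list alone. Cdkn2a, a cell cycle inhibitor that marks senescent cells, rose from 1.70 ± 0.708 to 7.22 ± 1.15 CPM (log2 2.08 ± 0.36, adjusted p = 0.0309). Gdf15, a stress-induced cytokine, rose by a log2 of 2.15 ± 0.35, and Glb1, lysosomal beta-galactosidase, by 0.51 ± 0.10.

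The unfolded protein and heat shock response fell by a small median of -0.20 (camera adjusted p = 0.0417, adjusted p = 0.679 with an estimated correlation), but its single called member, also the only 1 adjusted over the list alone, was Atf6, a sensor of endoplasmic reticulum stress, which rose from 56.3 ± 1.45 to 82.9 ± 7.59 CPM. That list lost its call without WT replicate 2 (adjusted p = 0.191), without NM1 KO replicate 1 (adjusted p = 0.139) and without NM1 KO replicate 2 (adjusted p = 0.219). When 1 library was left out, its median lay between -0.35 and -0.085. Atf6 had a log2 fold change of 0.56 ± 0.10, which was 0.33 at its lowest over the alternatives. Of 18 circadian clock genes, 2 rose and 1 fell, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0743, and 0.0299 without a filter and 0.00269 without WT replicate 2). Arntl and Npas2, activators of the clock, rose by log2 values of 1.13 ± 0.20 and 1.53 ± 0.30, and Per2, a repressor, fell from 71.7 ± 7.37 to 33.7 ± 4.90 CPM (log2 -1.09 ± 0.14). The time of day of sampling is not given in the sources used here. Erythroid genes fell (median -0.75, camera adjusted p = 0.000223, adjusted p = 0.613 with an estimated correlation). None of 8 was called by edgeR, 7 were lower when adjusted over the list alone, 7 had an unadjusted p under 0.05, and DESeq2 called 5 and limma-voom 2. Alas2, the first enzyme of heme synthesis in red cells, was at 27.3 ± 1.24 CPM in WT and 16.3 ± 3.35 in NM1 KO (adjusted p = 0.0566).

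The naming rule ranked called genes with a mean of at least 1 CPM and named symbols that are not pseudogenes. The largest rises by this rule were those of Ighg2c, Pnoc, Itgad, Stra6l, Atp6v0d2 and Zfp871. Called genes that the rule left out, such as Gm14461 (log2 7.18 ± 0.82) and Gm6685 (log2 6.91 ± 0.56), rose more than all of these but Ighg2c. Ighg2c, an immunoglobulin heavy chain constant region, was at 0.111, 0.0639 and 0.240 CPM in WT and 56.9, 5.31 and 18.5 CPM in NM1 KO (log2 7.61 ± 1.12, adjusted p = 0.0240), and reads shared with other heavy chain genes make its level uncertain. Pnoc, the precursor of the neuropeptide nociceptin, went from 0.0514 ± 0.0446 to 6.25 ± 2.61 CPM, and Itgad, an integrin chain of macrophages, from 0.398 ± 0.332 to 15.2 ± 8.95 CPM (log2 5.24 ± 0.67). Stra6l and the zinc finger gene Zfp871 rose by log2 values of 4.75 ± 0.93 and 4.66 ± 0.65. Among the largest falls by the same rule were those of Aqp5, Cyp26b1, Kcnt1, Faim2 and Nkx2-9. Called genes that the rule left out, such as Gm13301 (log2 -9.03 ± 0.72), fell more than all of these. Aqp5, a water channel, fell from 8.88 ± 8.01 to 0.639 ± 0.0788 CPM (log2 -3.79 ± 0.68). Its WT mean rested on WT replicate 2 (18.1 CPM, against 3.36 and 5.21), without which the log2 fold change was -2.74 (adjusted p = 0.0614), and it was called in 0 of 6 removals. Cyp26b1, an enzyme that degrades retinoic acid, fell from 14.7 ± 6.36 to 2.00 ± 0.582 CPM (log2 -2.88 ± 0.38). Faim2 fell from 6.62 ± 1.16 to 0.969 ± 0.0969 CPM, and Kcnt1 and the homeobox gene Nkx2-9 by 2.85 and 2.38 on the log2 scale.

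In all, 18 of 47 tested lists passed camera, 11 higher and 7 lower. With an estimated correlation 0 passed, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.287. By fry, 2 lists moved on balance in 1 direction, brown and beige adipocyte genes (adjusted p = 0.00624) and matrix proteases with TGF-beta signalling (adjusted p = 0.0272), and 31 changed in either direction. The largest list without a call was that of 59 nuclear-encoded oxidative phosphorylation subunits (median -0.084, camera adjusted p = 0.0859, and 0.0109 without WT replicate 3 and 0.0271 without NM1 KO replicate 2, 2 lower at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). The 48 cytosolic ribosomal proteins (median -0.045, camera adjusted p = 0.278) and the 34 chromatin architecture and histone modifier genes (median 0.025, camera adjusted p = 0.723) did not pass either.

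Some lists that did not pass held single calls, named here after their values were seen. Metrnl, a secreted adipocyte factor, rose by a log2 of 0.54 and was called with Gdf15 among 22 adipokines, whose median (-0.011) and mean (0.052) differed in sign. Mlxipl, the carbohydrate-responsive transcription factor, fell by 1.26 on the log2 scale among 25 genes of fatty acid and triglyceride synthesis (median -0.17), and Hcar1, the lactate receptor, by 0.92 among 22 genes of lipolysis (median -0.12). The synthesis list (camera adjusted p = 0.0524) passed as lower without a filter (adjusted p = 0.0191), without WT replicate 3 (adjusted p = 0.00264), without NM1 KO replicate 2 (adjusted p = 0.0232) and without NM1 KO replicate 3 (adjusted p = 0.0272). The lipolysis list (camera adjusted p = 0.0681) did so without a filter (adjusted p = 0.0257) and without WT replicate 2 (adjusted p = 0.0395). Without NM1 KO replicate 1 the median of the synthesis list was 0.049 (adjusted p = 0.267) and that of the lipolysis list -0.051 (adjusted p = 0.111). Without WT replicate 1 the synthesis list had a median of -0.058 (adjusted p = 0.161). The histone methyltransferase gene Kmt2d fell by 0.52 among the chromatin genes, and Myo1f, a class I myosin of leukocytes, rose by 1.30 among 7 class I myosins (median 0.26). Atf3 rose by 1.44 among 20 immediate early genes and C3ar1, the complement C3a receptor, by 1.48 among 18 complement genes. The medians of these lists were -0.074 and -0.034, their means 0.035 and 0.050, and camera's direction was higher for both (adjusted p = 0.855 and 0.723). Dendritic cell genes likewise had a median of -0.14, a mean of 0.24 and a higher direction (adjusted p = 0.568), and mast cell genes a median of 0.23 with a lower direction (adjusted p = 0.900). The 33 interferon-stimulated genes had a median of -0.38 (camera adjusted p = 0.0524), with 0 called by edgeR, 1 higher and 0 lower at an unadjusted p under 0.05, and 1 higher by each of DESeq2 and limma-voom. That list passed as lower without a filter (adjusted p = 0.0162), with the GC and length correction (adjusted p = 0.0362), and without WT replicate 1 (adjusted p = 0.00105), WT replicate 2 (adjusted p = 0.00326) or NM1 KO replicate 3 (adjusted p = 7.01e-06), and had a higher direction without WT replicate 3 (adjusted p = 0.996).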

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

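The GC and length correction was chosen after seeing the data, and the other alternatives before. Each of the 673 called genes kept its direction in all 17 alternatives in which it was tested, which the CPM filter (645) and the protein-coding set (622) limited. Their CPM ranges did not overlap in the main fit, so this was nearly fixed in advance. The number called stayed within 1.5 times of 673 under the other size factors (644 to 663), the other filters (917 without a filter, 659 with the CPM filter), non-robust dispersion (691), protein-coding genes (621) and the GC and length correction (764, keeping 77.0% of the calls). DESeq2 called 2193 genes (1313 higher and 880 lower) and limma-voom with quality weights 1648 (965 higher and 683 lower), and they shared 673 and 667 of the calls. Leaving out 1 library gave between 1 and 1654 calls, 1 to 1181 higher and 0 to 473 lower. Each such fit has fewer samples, but removing NM1 KO replicate 2 raised the count, and the cause was not tested. With the replicate number as a block, 336 genes were called (258 higher and 78 lower), 267 of them shared. Deviations of same-numbered libraries correlated at -0.0600, -0.0354 and 0.188, and those of libraries with unlike numbers between -0.0975 and 0.112. So few pairs cannot show whether the numbers pair the samples, and the labels do not say.

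Between 17 and 25 lists passed camera under every alternative that kept the preset correlation, against 18. Without a filter 12 lists were lower and with the block 11, against 7, and the cause was not tested. With the block, pro-inflammatory (adjusted p = 0.0377, higher), interferon (adjusted p = 0.000585, lower) and fatty acid and triglyceride synthesis genes (adjusted p = 0.0216, lower) were among the lists that passed besides. So were neutrophil genes (camera adjusted p = 0.00670, lower), which in the main fit had a median of -1.71 (camera adjusted p = 0.0701). None of the 6 tested was called, and 3 were lower adjusted over the list alone. Their medians against the WT mean were -0.57, 1.65 and -0.67 in WT replicates 1 to 3. Mitochondrially encoded proteins passed as lower with the GC and length correction (camera adjusted p = 5.29e-05). With an estimated correlation 0 lists passed, 0 higher and 0 lower, where 6 had an unadjusted p under 0.05 (4 higher and 2 lower), and by fry 2 passed, 2 higher and 0 lower, where 15 did. The lists that lost their call under a preset correlation were those of NK cells, with the CPM filter (adjusted p = 0.123) and without NM1 KO replicate 3, and of MHC class II and the unfolded protein response, each in 3 of 6 removals. Among named genes, the sign turned only for genes that were not called, as the called genes had ranges that did not overlap. Ccl2 lay between -0.20 and 1.20 on the log2 scale when 1 library was left out, Fasn between -0.49 and 0.065, Pparg between -0.091 and 0.25 and Ddx3y between -0.084 and 0.80. With limma-voom Fasn was at 0.088 and Pparg at -0.059, and with the GC and length correction Cebpa was at 0.12. Leaving out mitochondrial genes changed the sign of none of the 4 other library measures. The depth of 24677758 to 33537818 counts left Il6, Ucp1 and Xist too low to test.

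With 10 splits of the 6 libraries into 3 and 3, no share can go under 0.05. The real split gave the 673 calls and the highest other split 0 (104 to 1283 genes at an unadjusted p under 0.05 in the others, by edgeR alone), so 1 of the 10 gave as many. For lists at the preset correlation, 5 of the 10 splits, the real one included, gave as many as the real 18, and the highest other gave 20.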

Other observations

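The genes in the next paragraphs, the GC and length correction with its bound on shifts, and the tests of dilution, of macrophage makeup and of distance from Myo1c were chosen after the results they bear on had been seen. Further genes known from macrophages and endothelium were called. Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages, rose from 98.6 ± 5.12 to 561 ± 269 CPM (log2 2.51 ± 0.32, edgeR adjusted p = 0.0186), and C3ar1, the receptor for complement C3a, from 42.7 ± 5.44 to 119 ± 27.7 CPM. Soat1, which makes cholesterol esters, rose from 37.3 ± 3.31 to 87.1 ± 17.7 CPM, and Nceh1, which breaks them down, from 19.6 ± 0.798 to 69.8 ± 24.2 CPM. Of genes known from endothelial cells, S1pr1, the sphingosine-1-phosphate receptor, fell from 96.7 ± 10.9 to 51.0 ± 3.91 CPM, Rasip1, needed for vessel lumens, from 50.5 ± 7.17 to 17.1 ± 3.97 CPM, and Gpr4, a proton-sensing receptor, from 16.1 ± 0.856 to 3.89 ± 1.16 CPM. Each of these 7 was called in 13 of 17 alternatives, and in 2 of 6 when 1 library was left out.

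The smallest p belonged to Cbl, an E3 ubiquitin ligase that acts on receptor tyrosine kinases. It went from 1.71 ± 0.0509 CPM in WT to 35.1 ± 3.41 CPM in NM1 KO (log2 4.36 ± 0.15, edgeR adjusted p = 0.000126). Cbl was called in all 17 alternatives, with log2 fold changes between 4.09 and 4.42 and a highest adjusted p of 0.0123. Among markers of neighbouring tissues, Insl3, a Leydig cell hormone, fell from 2.12 ± 0.827 to 0.503 ± 0.0389 CPM, and Lgals4, a gut epithelial galectin, from 16.5 ± 3.40 to 6.74 ± 0.636 CPM. Cyp2e1, a cytochrome P450 of the hepatocyte list, fell by 2.11 on the log2 scale (adjusted p = 0.0397). Only 5 of the 14 genes of that list were high enough to test, so the fall of Cyp2e1 does not show liver tissue in the samples. Not all markers on the lists of neighbouring tissues fell. Of 5 tested hepatocyte genes 2 had a positive log2 fold change, though the list passed as lower without WT replicate 1 (adjusted p = 0.0454), and Ahsg of hepatocytes (log2 1.14, adjusted p = 0.161), Cela1 of the pancreas (log2 0.94, adjusted p = 0.0859) and Epcam of epithelia (log2 0.80, adjusted p = 0.589) were not called.

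The fall of vascular endothelium genes was weighed against 2 technical explanations. A GC and length bias would leave a median above -0.5 once the trend is removed. The median stayed at -1.02, where the correction shifted tested genes by -0.86 to 0.36 and the members by -0.26 to 0.27. The SE of this median was 0.070 from resampling the members, which are not independent, so it holds no spread between samples. Dilution of all resident cells by added immune cells would lower progenitor and adipocyte genes as much. The medians of progenitor (-0.044) and adipocyte genes (-0.28) lay above that of endothelium (-1.07) by 1.03 and 0.79, with permutation p of 0.00046 and 0.00058 over members, which are not independent. The lists were picked after their medians had been seen, so these p-values add nothing to the medians. Pericyte and smooth muscle genes (median -0.60) and mesothelial genes, which also fell, were not in this test. A lower share of endothelial RNA in NM1 KO fat is a candidate explanation that these values leave open, as are differences in how the tissue was dissected, which were not tested and could also move mesothelial and erythroid genes, whose medians of -0.49 and -0.75 were lower too.

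Lipid-associated macrophage genes had a median of 1.47 before and 1.27 after the GC and length correction, with shifts of -0.31 to 0.27 in the members. A GC and length bias would leave the median below 0.7. The SEs, from resampling the members, were 0.59 and 0.64, so the bound of 0.7 was not cleared by an SE. A part played by the bias cannot be told apart from genotype. More macrophages of the makeup seen in WT would raise resident genes with the general markers, but their medians were -0.995 and 0.56 (permutation p of 3e-05 over members, which are not independent). These lists too were picked after their medians had been seen, so this p-value adds nothing to the medians.

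There were 62 genes called with a log2 fold change of at least 3 in size. The GC and length correction shifted no tested gene by more than 0.86 on the log2 scale, so the trend that it removes is not the whole cause of such sizes. Of the 62, 7 lay within 20 Mb of Myo1c, or 11.3% against 3.36% of tested genes (Fisher's exact p of 0.00463), while windows of 10 and 50 Mb gave exact p of 0.372 and 0.0458. Strain variants carried along with the targeted locus may account for such neighbours (Gm12247, Fam183b, Hist3h2ba, 2610507I01Rik, Mfap4, Nlrp1a and Ccl3). Chromosome 4, however, held 11 of the 62, or 1.14% of its 962 tested genes, against 9, or 0.691% of 1302, on chromosome 11. These 11 may not all be separate changes. Gm13301, Gm5859 and Gm10600 lie side by side there (42216908 to 42242685), and all were lower. Gm13301 was at 2.66, 2.11 and 1.96 CPM in WT replicates 1 to 3 and at 0 in every NM1 KO library. The 55 outside the window of 20 Mb lie farther away, on other chromosomes or, for 3, without a position in the annotation. Background variants there were not tested.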
